A study of Mus musculus with 10 samples.

How the data were processed

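RNA sequencing of total RNA from 10 placentas of embryonic day 15.5 was analysed, 6 labelled knockout and 4 labelled control. Per the labels' protocols, RNA was extracted with a column kit and libraries were built with a NEBNext Ultra kit. Per the submitters' processing notes, reads were handled with bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2, with the genome build GRCm38.p6. The order of these steps, the strand setting, the treatment of reads that map to several genes, the gene filter and the tool that gave the size factors are not given in the sources used here. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart, and paralogs can share or lose reads.

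The deposited table holds, for 15344 genes and 10 libraries, a coverage signal: normalised read counts, that is, each gene's reads divided by 1 size factor per library. Every deposited value was a whole multiple of its library's step, so whole reads were recovered by dividing by that step (100% of values whole within 0.01 of a read). Median-of-ratios factors recomputed from these reads differed from the inverse of the steps by at most 5.48e-11. The 10 libraries held 20462809 to 26751556 recovered reads, and the smallest total of any listed gene over all libraries was 101 reads, so genes below that were not analysed here. At this depth counting error is small beside the spread between libraries for all but the lowest genes. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads.

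Gene symbols and coordinates come from the mouse GENCODE annotation of GRCm38, and 15317 of the 15344 gene identifiers had a symbol. The annotation version used by the authors is not given in the sources used here.

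The design was fixed before the data were examined, together with the gene lists, the rule for named genes and the main alternatives. Knockout was compared with control in 1 linear model over all 10 libraries with limma 3.58.1 (R 4.3.3), on log2(value + 1) with a mean-variance trend, without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean of at least 10 over all libraries were kept, which left 15321 and removed 23. The deposited values are not raw counts, so edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered whole reads as alternatives, and limma-voom was added later. DESeq2 gave no adjusted p for 105 genes, which were left as missing.

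Gene lists covered iron handling, stress responses, transport, growth and the cell types a placenta sample can hold (28 lists tested, 417 of 449 listed genes matched). Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. Camera in fits with other libraries or covariates used the preset correlation only. A list of sex-linked genes was read as values only. Camera compares a list with the other genes, while fry asks whether the list's own genes move one way. For single members, p-values were also adjusted over the list alone. A list score is the mean log2 value of its members in a library.

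The genes named in the text follow a fixed rule. They are Slc40a1, the genes past the adjusted threshold with the largest changes or, where fewer than 5 pass, the 5 smallest p-values in each direction, up to 4 members with the smallest p from every list, and every measured member of the iron uptake and the iron storage and export lists, leaving out predicted genes. Genes outside the rule are said to have been named after their values were seen.

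Single measures were compared with exact two-sided permutation tests over all 210 splits of the 10 libraries (scipy 1.17.1), whose smallest possible p is 0.00952. Among these measures only Slc40a1 was planned for this test. A list's mean log2 fold change and its SE came from a linear model of the members' mean log2 value per library, added after the data were seen. Principal components used the 500 most variable genes. Pairs of libraries within a group were compared by a chi-square statistic over genes with at least 20 reads. Alternatives changed the pseudocount, the filter, the scaling, the test, sample weights, covariates for erythroid or decidua list scores, and the libraries included, leaving out each in turn.

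The tests were tried on simulated counts with the real group sizes and library sizes, over 15175 genes kept by the filter for limma. The changed genes were drawn only from genes with a mean of at least 50, so the rates do not cover genes with fewer reads. At an adjusted threshold of 0.05, limma recovered 50.8% of 1.5-fold, 79.2% of 2-fold and 95.4% of 4-fold changes, with 8 false calls among 159. DESeq2, over 15344 genes, recovered 66.7%, 87.5% and 98.5%, with 37 false calls among 206. Camera recovered the raised list and called 0 of 25 lists that shared no member with it. The simulated libraries carried no difference in tissue composition, and each gene was drawn independently. The run therefore could not show false calls of lists whose members move together. In the real libraries the estimated correlation reached 0.62 for the proliferation and interferon lists and 0.89 for yolk sac markers.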

Results

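Gene expression was measured by RNA sequencing in 10 mouse placentas collected at embryonic day 15.5, 6 labelled ferroportin knockout and 4 labelled control. All were labelled male and of the 129S6/SvEvTac strain, an inbred mouse strain. Ferroportin, the product of Slc40a1, is the known cellular iron exporter, and the placenta passes iron from the maternal to the fetal circulation. Each library held 20462809 to 26751556 reads in the listed genes, with 24678985 ± 1344000 reads (SD, n = 4) in the control and 22134518 ± 2369994 (SD, n = 6) in the knockout-labelled libraries, a difference within the spread between libraries (exact two-sided permutation test, p = 0.114). The Y-linked gene Ddx3y lay between 953 and 1257 normalised reads in all 10 libraries, and Xist, the RNA of the inactive X chromosome, between 24.0 and 121. The labels give each library its own placenta but name no litter or dam, so p-values measure the spread between these samples. The sample titles also carry bracketed codes whose meaning is not given, so shared litters or batches cannot be told.

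The targeted gene was examined first. Slc40a1 (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523 on the minus strand of GRCm38) had 12793 ± 1194 normalised reads (SD, n = 4) in the control libraries and 11636 ± 2683 (SD, n = 6) in the knockout-labelled libraries. The control libraries held 14548, 12222, 12493 and 11908 and the knockout-labelled libraries 7270, 10587, 10840, 13680, 12643 and 14798. The log2 fold change of knockout minus control was -0.17 (SE 0.17, limma adjusted p = 0.996 over all genes tested), and an exact two-sided permutation test gave p = 0.457, where the smallest p the design allows is 0.00952. The labels do not say which part of Slc40a1 was deleted, and reads summed over a whole gene cannot show the loss of single exons, so these values check neither the knockout nor the labels. Every direction below is therefore drawn between libraries labelled knockout and libraries labelled control.

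The main comparison asked which placental genes differed with the ferroportin genotype. Among the genes of the lists fixed in advance, the transferrin receptor Tfrc fell in the knockout-labelled libraries, from 8754 ± 6167 (SD, n = 4) to 2256 ± 324 (SD, n = 6) normalised reads, and the antioxidant enzyme gene Nqo1 rose from 59.9 ± 11.3 to 190 ± 52.0, both adjusted over the list alone. The adult globin genes Hba-a1, Hbb-bt and Hbb-bs fell and the embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x rose, again adjusted over the list alone. Over all 15321 genes tested, limma found 0 genes past an adjusted p of 0.05, with 776 genes at an unadjusted p under 0.05 (412 higher and 364 lower in the knockout-labelled libraries) where 766 are expected by chance. On the recovered whole reads, edgeR's quasi-likelihood test found 0 genes (804 unadjusted), limma-voom 0 (800 unadjusted) and DESeq2 68, of which 48 were higher and 20 lower. Knockout library 1 stood apart from the other 9, and without it limma found 14 genes, 12 higher and 2 lower. Leaving out control library 4 gave 1 gene, Tfrc (adjusted p = 0.0094 over all genes). Leaving out knockout library 3 gave Nqo1 (0.0495), and leaving out knockout library 6 gave Capn12 (0.0113).

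The smallest p-values among the genes with more reads in the knockout-labelled libraries belonged to Capn12, Nqo1, Adh7, mt-Ty and Cat, none of which passed over all genes tested. Capn12, a calpain protease gene (chromosome 7, 28881422 to 28893563), had 68.4 ± 5.57 normalised reads (SD, n = 4) in the control and 224 ± 78.3 (SD, n = 6) in the knockout-labelled libraries, which differed by a log2 fold change of 1.64 (SE 0.21, limma adjusted p = 0.0634, above every control in 6 of 6). Nqo1, a quinone reductase gene (chromosome 8, 107388225 to 107403206), had a log2 fold change of 1.62 (SE 0.21) with the same adjusted p. Cat, which encodes the peroxide-degrading enzyme catalase, had 918 ± 55.3 and 1392 ± 204 normalised reads. Adh7, an alcohol dehydrogenase gene, had 5.22 ± 0.542 and 22.6 ± 9.11. The mitochondrial transfer RNA gene mt-Ty had 27.2 ± 7.12 and 60.5 ± 6.88, on a gene of only 67 bases. In the other direction stood Tfrc, Bpgm, Pdpn, Itpka and Fgf18, also not past the threshold over all genes. Bpgm, whose enzyme makes bisphosphoglycerate in red cells and placenta, had 907 ± 236 and 474 ± 81.7 normalised reads. Pdpn, a podoplanin gene of lymphatic and stromal cells, had 822 ± 82.5 and 607 ± 45.4. Itpka, an inositol phosphate kinase gene, had 1074 ± 188 and 686 ± 88.3, and the growth factor gene Fgf18 22.2 ± 7.16 and 5.5 ± 2.47. For Bpgm, Pdpn, Itpka and Fgf18 all 6 knockout-labelled libraries lay below all 4 controls, which adds no separate support because these genes were chosen by their small p-values.

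**Figure D1:**
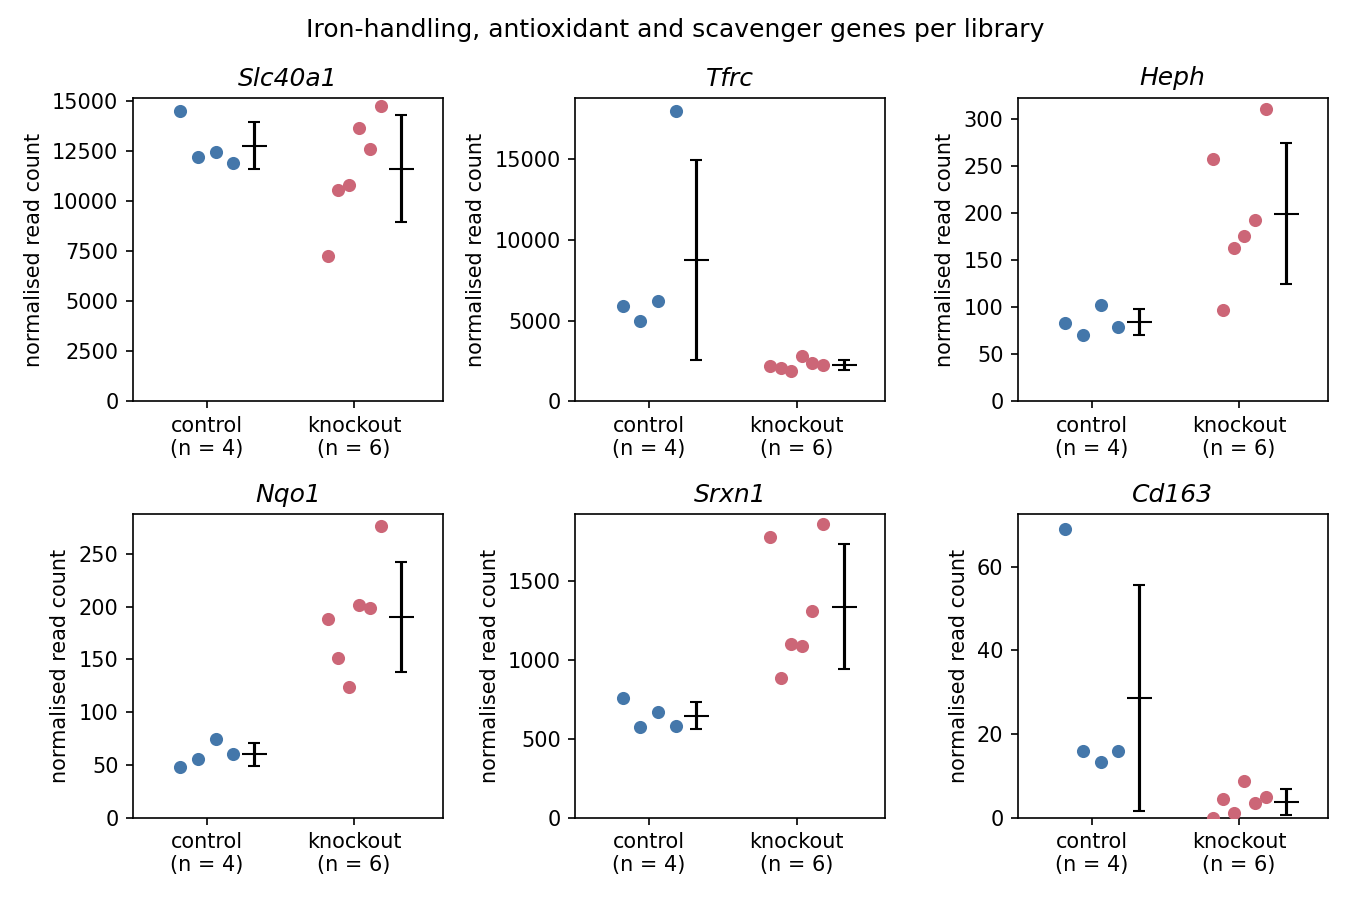
Normalised read counts (vertical axes, linear, from 0) of 6 genes in each library, with controls in blue (n = 4) and knockout-labelled libraries in red (n = 6); the bars give the group mean and SD. For Tfrc and Cd163 all 6 knockout-labelled values lie below all 4 controls, for Nqo1 and Srxn1 all 6 lie above, and for Heph 5 of 6 do, while the Slc40a1 values overlap.

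Genes of iron uptake were compared next, since the exporter was the target. Of 12 measured members, 1 fell, 0 rose and 11 did not pass, adjusted over the list alone, and 0 passed over all genes tested. The member that fell was Tfrc (chromosome 16, 32608920 to 32632794), which encodes the receptor for transferrin-bound iron and whose messenger RNA is known to be broken down when cell iron is high. Its log2 fold change was -1.75 (SE 0.30, limma adjusted p = 0.00109 over the list alone and 0.347 over all genes). All 6 knockout-labelled libraries lay below all 4 controls (exact two-sided permutation test, p = 0.00952, the smallest the design allows). That test was planned for Slc40a1 only, complete separation fixes its p, and it was not adjusted for the number of genes, so it adds no separate support. Control library 4 held 17972 normalised reads of Tfrc against 4972 to 6182 in the other 3 controls, and without it the log2 fold change was -1.34 (SE 0.12). Tfrc is also abundant in red cell precursors, and the erythroid markers described below moved with it. Among the other members, the ferrireductase gene Steap3 had 1939 ± 350 (SD, n = 4) and 2364 ± 310 (SD, n = 6) normalised reads, and the divalent metal transporter gene Slc11a2 1523 ± 108 and 1417 ± 150. The remaining log2 fold changes ran from -0.34 for Lrp1 through -0.27 for Slc25a37, -0.25 for Slc39a8, -0.15 for Slc39a14, -0.01 for Slc46a1, 0.04 for Slc25a28, 0.06 for Steap2 and 0.10 for Mcoln1 to 0.43 for Steap4, a gene whose knockout-labelled mean of 80.4 ± 138 rested on 362 normalised reads in knockout library 1. As a group the list was not set apart from other genes (camera adjusted p = 0.273).

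Of 9 measured members of iron storage and export, 1 rose, 0 fell and 8 did not pass, adjusted over the list alone, and 0 passed over all genes tested. Heph, which encodes the ferroxidase hephaestin that works with ferroportin in iron export, rose from 84.0 ± 13.8 (SD, n = 4) to 199 ± 74.9 (SD, n = 6) normalised reads, a log2 fold change of 1.16 (SE 0.27, limma adjusted p = 0.0119 over the list alone, above every control in 5 of 6). Without control library 2 its log2 fold change was 1.08 with an adjusted p of 0.0502. The ferritin light chain gene Ftl1 had 28553 ± 2399 and 34277 ± 5306 normalised reads and the ferritin heavy chain gene Fth1 12015 ± 3982 and 11894 ± 3198. The ferritin autophagy receptor gene Ncoa4 had a log2 fold change of 0.20 (SE 0.08), Abcg2 0.22, Cp, the ceruloplasmin gene, 0.11, Flvcr1 0.07, Pcbp1 0.02 and Pcbp2 -0.03. The list as a group lay higher (camera adjusted p = 0.00458, median log2 fold change 0.11), with an adjusted p = 0.143 with an estimated correlation and an adjusted fry p of 0.0192 for one direction. With the erythroid list score as a covariate this call ended (median 0.0985, camera adjusted p = 0.259), the list's mean log2 fold change falling from 0.22 (SE 0.07) to 0.16 (SE 0.07). Leaving out 1 library at a time, the list's median ran from 0.058 without control library 4 to 0.22 without knockout library 2, while the call held. Iron sensing and hepcidin genes did not pass as a list (13 measured, 0 past the threshold over the list alone, camera adjusted p = 0.211). Without knockout library 1 the list lay higher at the preset correlation (camera adjusted p = 0.0061), where the estimated correlation with all 10 libraries was 0.12. In that fit 3 members rose over the list alone, among them the signalling inhibitor gene Smad6 (limma adjusted p = 0.0284, and 0.0448 without control library 1). In all 10 libraries Bmp2, a growth factor gene upstream of hepcidin, had 157 ± 23.8 and 227 ± 68.4 normalised reads.

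Targets of NRF2, the transcription factor that switches on antioxidant and detoxification genes, had the smallest camera p of the 28 lists. Of 19 measured members, 6 rose, 0 fell and 13 did not pass, adjusted over the list alone, and 0 passed over all genes tested. Nqo1 rose 3.08-fold (limma adjusted p = 0.000157 over the list alone). Srxn1, which encodes sulfiredoxin, rose from 644 ± 85.9 (SD, n = 4) to 1336 ± 396 (SD, n = 6) normalised reads, a log2 fold change of 1.01 (SE 0.20, adjusted p = 0.00299 over the list alone, above every control in 6 of 6). The pentose phosphate pathway genes Taldo1 and Pgd rose by log2 fold changes of 0.28 (SE 0.06) and 0.37 (SE 0.09). The heme oxygenase gene Hmox1, also on this list, had 2915 ± 243 and 3443 ± 509 normalised reads and did not pass. In all, 17 of the 19 members had a log2 fold change above 0, with a median of 0.23 (camera adjusted p = 1.22e-13). The call was lost at an adjusted p = 0.0558 with an estimated correlation, while fry gave an adjusted p of 0.0192 for one direction. Without knockout library 1, 7 members rose, and without control library 1, 10 members passed.

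**Figure D2:**
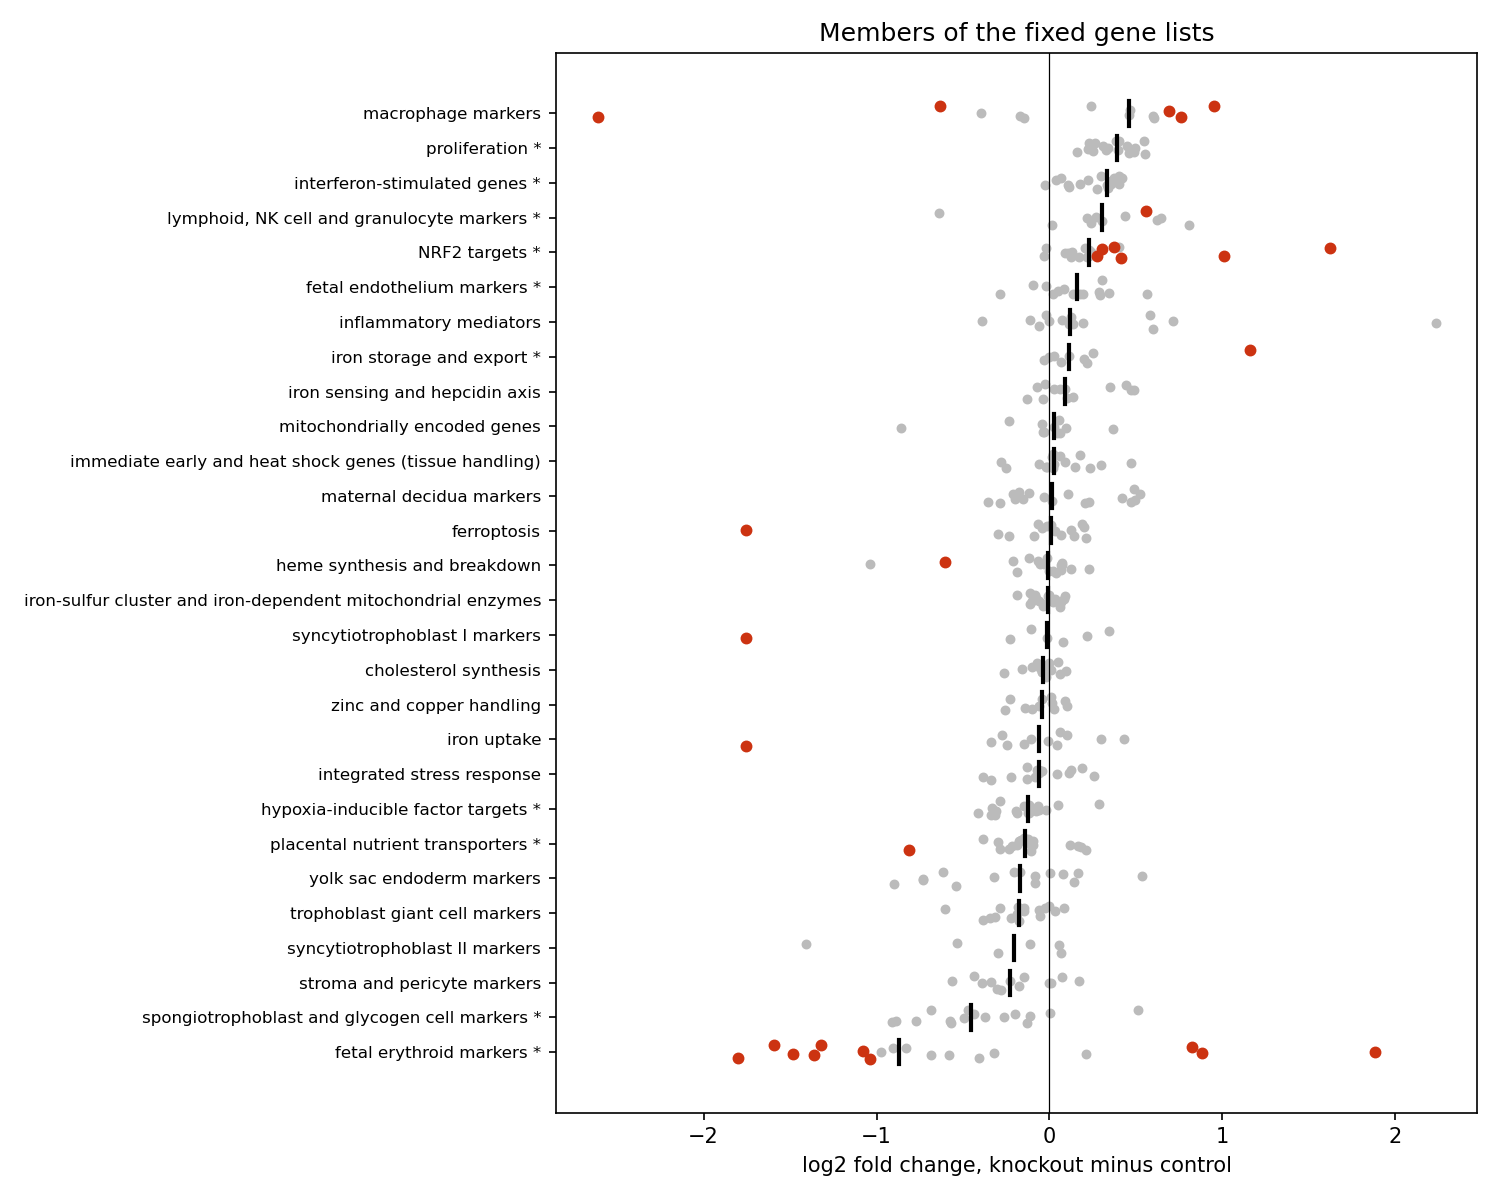
Log2 fold change of knockout minus control (horizontal axis) of each measured member of the 28 gene lists fixed in advance (rows), from 6 and 4 libraries. Red points passed an adjusted p of 0.05 over the list alone, grey points did not, black bars mark list medians, and a star marks the 10 lists past camera's threshold; 17 of 19 NRF2 targets lie above 0.

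Red cell genes moved in opposite directions. Of 18 measured erythroid markers, 3 rose, 7 fell and 8 did not pass, adjusted over the list alone, and 0 passed over all genes tested. The embryonic beta-like globin gene Hbb-y rose from 1251 ± 384 (SD, n = 4) to 5249 ± 3665 (SD, n = 6) normalised reads, a log2 fold change of 1.88 (SE 0.41, limma adjusted p = 0.00884 over the list alone, above every control in 6 of 6). The other embryonic globin genes Hbb-bh1 and Hba-x, named after their values were seen, rose by log2 fold changes of 0.88 (SE 0.25) and 0.82 (SE 0.25). Hba-a1, an adult alpha globin gene, fell from 47447 ± 15589 to 16824 ± 8334 normalised reads. Hbb-bt, an adult beta globin gene, fell from 9419 ± 3711 to 2903 ± 1339, and both had all 6 knockout-labelled libraries below all 4 controls. Sptb, the red cell spectrin gene, fell from 242 ± 10.1 to 106 ± 40.8. Hbb-bs, Hba-a2 and Slc4a1, the red cell anion exchanger gene, also named after their values were seen, fell by 1.36, 1.08 and 1.49 on the log2 scale. Hba-a2 lost its call without control library 1 (log2 fold change -0.69, adjusted p = 0.0869 over the list alone), control library 4 (-1.03, 0.0761) or knockout library 3 (hardly changed, 0.0573), and without the 3 libraries high in yolk sac or decidua markers (-0.44, SE 0.24, 0.126). Alas2, the erythroid heme synthesis gene, fell with this list (log2 fold change -1.04, SE 0.40, adjusted p = 0.0431 over the list alone). The adult pairs Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are nearly identical copies that share reads, so the split within each pair is uncertain. Adult globin RNA in a placenta can be fetal or maternal. As a group the list lay lower (camera adjusted p = 2.16e-05, median log2 fold change -0.87), with an adjusted p = 0.405 with an estimated correlation. Knockout library 1 was the lowest on this list (mean log2 value 7.22), and without it the median was -0.63 and the mean log2 fold change went from -0.59 (SE 0.30) to -0.36 (SE 0.13, camera adjusted p = 0.00118).

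The balance of embryonic and adult globins differed between the groups. The mean log2 value of the 3 embryonic globin genes minus that of the 4 adult globin genes was -5.31 ± 0.75 (SD, n = 4) in the control and -2.65 ± 0.95 (SD, n = 6) in the knockout-labelled libraries, a difference of 2.65 (SE 0.54, 6.29-fold), with all 6 above all 4 controls (exact two-sided permutation test, p = 0.00952). This measure was chosen after the globin values were seen. Among 18 measured genes of heme synthesis and breakdown, 1 fell, 0 rose and 17 did not pass, adjusted over the list alone (0 over all genes tested, camera adjusted p = 0.501). That gene was Fech, the ferrochelatase that inserts iron into heme, which fell from 1520 ± 312 (SD, n = 4) to 992 ± 107 (SD, n = 6) normalised reads (log2 fold change -0.60, SE 0.12, limma adjusted p = 0.00709 over the list alone, below every control in 6 of 6). Its call ended with a block over replicate numbers 1 to 4, which takes 8 libraries (log2 fold change -0.58, wider SE of 0.14, adjusted p = 0.0899 over the list alone).

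**Figure D3:**
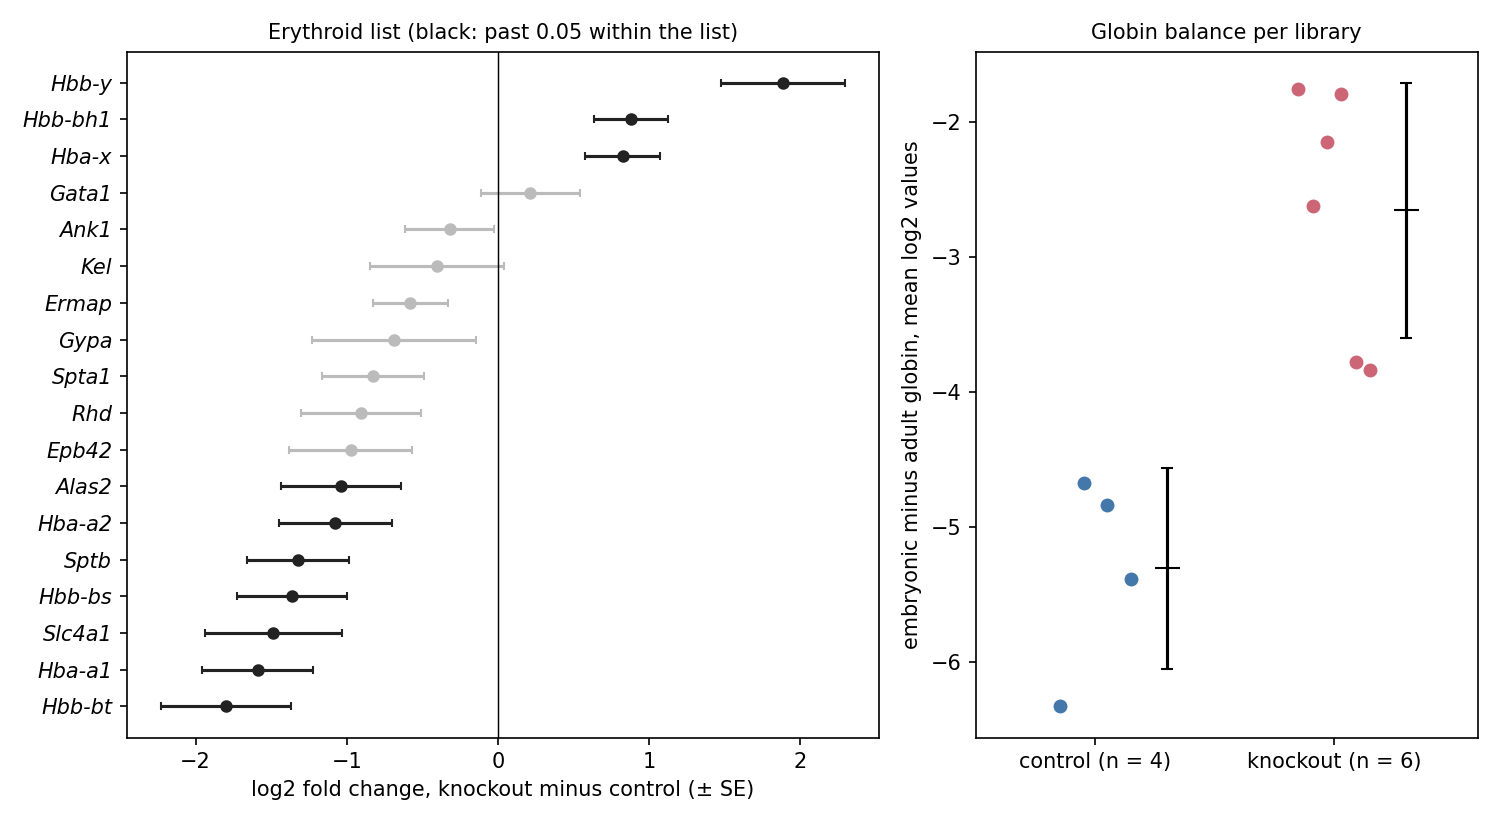
Left, log2 fold change of knockout minus control with its standard error for the 18 measured erythroid genes, black where past an adjusted p of 0.05 over the list alone. Right, the mean log2 value of 3 embryonic minus 4 adult globin genes in each library, with group mean and SD; all 6 knockout-labelled libraries (red) lie above all 4 controls (blue).

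Macrophage markers moved both ways. Of 13 measured members, 3 rose, 2 fell and 8 did not pass, adjusted over the list alone, and 0 passed over all genes tested. Adgre1, which encodes the macrophage surface protein F4/80, rose from 46.8 ± 16.8 (SD, n = 4) to 88.7 ± 19.7 (SD, n = 6) normalised reads, a log2 fold change of 0.95 (SE 0.24, limma adjusted p = 0.0154 over the list alone, above every control in 6 of 6). The complement genes C1qc and C1qb rose by log2 fold changes of 0.69 (SE 0.22) and 0.76 (SE 0.25), C1qb being named after its values were seen. Cd163, the scavenger receptor gene for hemoglobin bound to haptoglobin, fell from 28.5 ± 27.0 to 3.77 ± 3.08 normalised reads, with 69.0 in control library 1 against 13.2 to 16.0 in the other 3 controls, and was at 0 in knockout library 1. The factor XIII subunit gene F13a1 fell from 205 ± 22.1 to 134 ± 31.7. The list as a group was not set apart (camera adjusted p = 0.23). Only 3 members passed without control library 3, control library 4 or knockout library 6, each of which ended the calls of C1qc and C1qb at log2 fold changes of 0.58 to 0.73 (C1qc also without control library 2, at an adjusted p of 0.0519). Without control library 1 the list as a group lay higher at the preset correlation (camera adjusted p = 0.00801), where the estimated correlation with all 10 libraries was 0.19. With the erythroid list score as a covariate, none of these 5 genes passed and 1 other member did. Adgre1 then had a log2 fold change of 0.73 (SE 0.28, adjusted p = 0.104 over the list alone) and F13a1 of -0.47 (SE 0.20) against -0.63 (SE 0.18), smaller changes with wider SEs. Those of Cd163 (from -2.61, SE 0.66, to -1.51, SE 0.58), C1qc (to 0.36, SE 0.20) and C1qb (to 0.50, SE 0.27) shrank more.

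Among 11 measured lymphoid, natural killer cell and granulocyte markers, 1 rose, 0 fell and 10 did not pass, adjusted over the list alone (0 over all genes tested). Nkg7, a gene of cytotoxic granules, rose from 58.3 ± 4.23 (SD, n = 4) to 87.2 ± 14.1 (SD, n = 6) normalised reads (log2 fold change 0.56, SE 0.15, limma adjusted p = 0.0364 over the list alone), a call that was lost when any 1 of 8 libraries was left out, among them knockout library 1 (adjusted p = 0.0539), with log2 fold changes of 0.49 to 0.59. The list as a group lay higher (camera adjusted p = 0.00646), with an adjusted p = 0.405 with an estimated correlation, an adjusted p of 0.235 without knockout library 1 (median 0.19) and of 0.0801 without control library 4 (0.27). With the erythroid score as a covariate the list's median went from 0.31 to 0.13 and its mean from 0.32 (SE 0.35) to -0.22 (SE 0.28, adjusted p = 0.973). Nkg7 then had a log2 fold change of 0.53, close to 0.56, but its SE widened from 0.15 to 0.19 and it did not pass (adjusted p = 0.195 over the list alone). Without the 3 libraries high in yolk sac or decidua markers the list did not pass (median 0.28, mean 0.080, SE 0.21, adjusted p = 0.176). Nor did Nkg7, with a log2 fold change of 0.65 and a wider SE of 0.19 (adjusted p = 0.0615).

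Among 20 measured placental nutrient transporters, 1 fell, 0 rose and 19 did not pass, adjusted over the list alone (0 over all genes tested). Slc2a3, a glucose transporter gene, fell from 1734 ± 180 (SD, n = 4) to 1021 ± 292 (SD, n = 6) normalised reads (log2 fold change -0.81, SE 0.20, limma adjusted p = 0.0403 over the list alone, below every control in 6 of 6), and the adjusted p lay above 0.05 when any 1 of 7 libraries was left out, up to 0.151 without control library 4. In those 7 fits its log2 fold change was -0.76 to -0.88, with larger SEs (0.22 to 0.23). The amino acid transporter gene Slc7a5 had 17193 ± 1839 and 13242 ± 2091 normalised reads. The list as a group lay lower (camera adjusted p = 0.00458, median log2 fold change -0.14), with an adjusted p = 0.405 with an estimated correlation and of 0.0779 without knockout library 1. The call also ended with the erythroid score as a covariate (adjusted p = 0.973) and without the 3 libraries high in yolk sac or decidua markers (0.256). In these 3 fits the median hardly moved (-0.14, -0.14 and -0.13) but the members spread apart. The list's mean log2 fold change went from -0.14 (SE 0.10) to -0.085 (SE 0.07) without knockout library 1, 0.018 (SE 0.06) with the covariate and -0.054 (SE 0.08) without the 3 libraries. The covariate also ended the call of Slc2a3, whose log2 fold change shrank to -0.51 (SE 0.19, adjusted p = 0.0615 over the list alone).

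In 5 further lists no member passed, over the list alone or over all genes tested, while the group passed camera's preset test. Proliferation genes lay higher, with 18 of 18 log2 fold changes above 0 and a median of 0.39 (camera adjusted p = 3.09e-09), and an adjusted p = 0.405 with an estimated correlation. Among them the replication genes Mcm3 and Pcna had log2 fold changes of 0.40 (SE 0.14) and 0.23 (SE 0.08). Without knockout library 1, 11 proliferation genes and 7 endothelial genes rose adjusted over the list alone. Control library 1 had the lowest proliferation score, a mean log2 value of 7.21 against 7.8 to 7.84 in the other controls, and without it the proliferation median was 0.23 (adjusted p = 9.17e-05). Interferon-stimulated genes lay higher (median 0.33, camera adjusted p = 2.98e-06), with an adjusted p = 0.461 with an estimated correlation. Isg15 had 546 ± 71.9 (SD, n = 4) and 739 ± 147 (SD, n = 6) normalised reads and Rtp4 587 ± 45.7 and 770 ± 153. The interferon list's mean log2 value was 9.9 in knockout library 1 against 8.75 to 8.88 in the other 5 knockout-labelled libraries. Without that library its median was 0.13 (adjusted p = 0.0196), and with the erythroid score as a covariate its direction turned (median -0.050) and the call ended (adjusted p = 0.509). Fetal endothelium markers lay higher (median 0.16, camera adjusted p = 0.00646), with an adjusted p = 0.521 with an estimated correlation, 0.0742 without knockout library 4 (median 0.094) and 0.0757 without knockout library 6 (median 0.087). The median was also lower in the 8 libraries with replicate numbers 1 to 4 (0.080, adjusted p = 0.143, and 0.0880 with a block). It was higher without knockout library 1 (0.28), without the 3 libraries high in yolk sac or decidua markers (0.38, adjusted p = 8.51e-09) and with the erythroid covariate (0.64, adjusted p = 5.40e-10). The endothelial receptor gene Eng had 1597 ± 201 and 2434 ± 640 normalised reads. Hypoxia-inducible factor targets lay lower, with 18 of 20 log2 fold changes below 0 and a median of -0.12 (camera adjusted p = 9.74e-06), and an adjusted p = 0.191 with an estimated correlation. Control library 1 was the highest control on this list, and without it the median was -0.090 and the mean log2 fold change went from -0.15 (SE 0.08) to -0.083 (SE 0.07, adjusted p = 0.0048). The glycolysis regulator genes Pdk1 and Pfkfb3 had log2 fold changes of -0.19 (SE 0.06) and -0.33 (SE 0.11), and Pfkfb3 passed over the list alone without knockout library 6 (adjusted p = 0.0482). Spongiotrophoblast and glycogen cell markers, of the junctional zone between labyrinth and decidua, lay lower (median -0.45, camera adjusted p = 3.57e-05), with an adjusted p = 0.405 with an estimated correlation. Their median was -0.25 without control library 1 and -0.28 without knockout library 6, where the call held, and -0.73 with the erythroid covariate. Aldh1a3 had 2668 ± 252 and 1524 ± 647 normalised reads and Psg19 21442 ± 9247 and 12175 ± 6132, the latter a member of a gene family whose copies can share reads. Aldh1a3 passed over the list alone without knockout library 3 (adjusted p = 0.0418) or knockout library 5 (0.016).

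The other lists did not pass camera with all 10 libraries. Trophoblast giant cell markers had an adjusted p of 0.0558, stroma and pericyte markers 0.106, syncytiotrophoblast II markers 0.377, syncytiotrophoblast I markers 0.524, maternal decidua markers 0.501 and yolk sac endoderm markers 0.501. Without knockout library 1 the giant cell list (adjusted p = 0.000525) and the yolk sac list (1.83e-09) lay lower at the preset correlation. The yolk sac list had an estimated correlation of 0.89 with all 10 libraries. The giant cell list also lay lower without control library 2 (0.0184), control library 3 (0.0427) or knockout library 2 (0.0274). The stroma list lay lower without control library 1 (0.00835), knockout library 4 (0.0201) or knockout library 5 (0.00759). Without control library 1 the decidua (0.00683), inflammatory (0.0179) and tissue handling (0.0105) lists lay higher. All these fits with libraries left out used the preset correlation. With all 10 libraries the estimated correlation was 0.50 for decidua, 0.47 for tissue handling, 0.29 for inflammatory, 0.28 for giant cell and 0.25 for stroma markers. These p-values may therefore be far too small. Syncytiotrophoblast I markers held Tfrc as the 1 member that fell over the list alone, and the fusion gene Syna, with 2706 ± 569 (SD, n = 4) and 3409 ± 450 (SD, n = 6) normalised reads, did not pass, except without control library 3 (adjusted p = 0.00675). The syncytiotrophoblast II genes Synb and Gcm1 had 139 ± 66.5 against 62.7 ± 31.1 and 1286 ± 55.7 against 1185 ± 565. Integrated stress response genes had a camera adjusted p of 0.463, inflammatory mediators 0.289, zinc and copper handling 0.501, iron-sulfur cluster genes 0.542, cholesterol synthesis 0.501, and immediate early and heat shock genes, which respond to tissue handling, 0.367. Ferroptosis genes (adjusted p = 0.501) again held Tfrc as the 1 member that fell over the list alone, with a median of 0.01 and a mean of -0.10 on the log2 scale. Mitochondrially encoded genes had a median of 0.03, a mean of -0.05 and an adjusted p of 0.906. With estimated correlations, 0 of the 28 lists passed camera (smallest adjusted p = 0.0558), and fry called 2 lists in one direction, NRF2 targets and iron storage and export.

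The libraries did not separate by genotype on their main axes of variation. The first principal component of the 500 most variable genes held 35.9% of the variance and set knockout library 1 (-46.3) apart from the other 9 (-14.6 to 11.2). Yolk sac endoderm markers were far higher in knockout library 1 than in the other 5 knockout-labelled libraries, with a mean log2 value of 11.1 against 6.21 to 7.11, and control library 3 stood at 8.63. The second component held 19.8% and set control library 1 (-24.2) and knockout library 5 (-24.6) apart, which also had the highest mean log2 values of the maternal decidua list, 8.96 and 9.61, against 7.33 to 7.96 in the other 8. Pairwise correlations of log2 values ran from 0.951 to 0.991 across genes, and no pair of libraries within a group agreed within counting noise (chi-square per degree of freedom 10.2 to 137). Without those 3 libraries, a fit added after the data were seen, limma found 21 genes, 19 higher and 2 lower. In the same fit 8 NRF2 targets rose adjusted over the list alone, and Heph no longer passed (log2 fold change 1.04, SE 0.32, adjusted p = 0.0871).

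**Figure D4:**
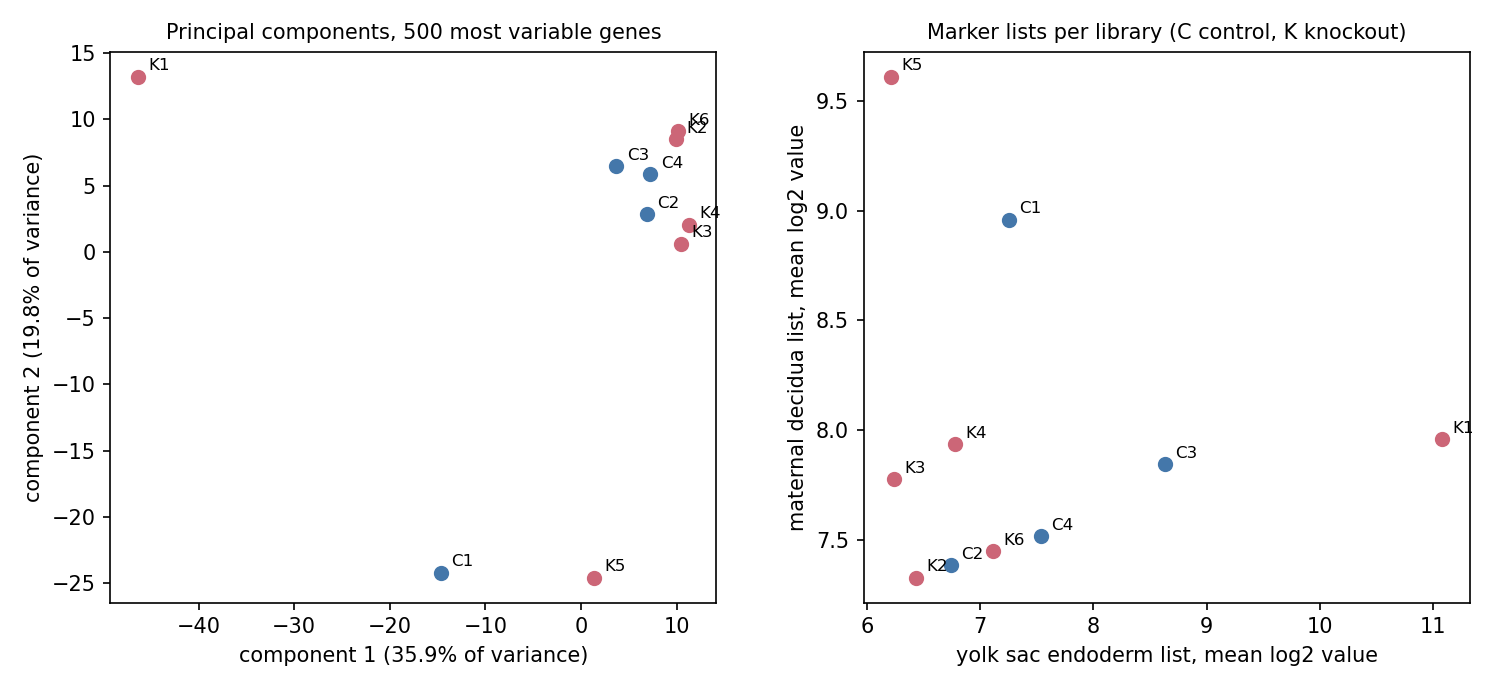
Left, the 10 libraries on the first and second principal components (35.9% and 19.8% of the variance). Right, mean log2 values of the yolk sac endoderm list (horizontal) and the maternal decidua list (vertical) per library, controls in blue and knockout-labelled libraries in red, each point named by group letter and replicate; knockout library 1 stands at 11.1 on the yolk sac list, and control library 1 and knockout library 5 have the highest decidua values, 8.96 and 9.61.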

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

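The tests of Tfrc, NRF2 targets, lower blood content, maternal blood, yolk sac, labyrinth cells and fetal liver below were chosen only after the result was seen, as were the gene names Afp, Depp1, Ldb2 and Tmem100. Within the controls or the knockout-labelled libraries, a sample was taken as far from the others when its gap to the nearest exceeded Dixon's critical value. Chance flags about 1 in 20 groups, 11 of the 220 groups examined, and 38 were found, 17 of them in knockout library 1 and 10 in control library 1. The groups were neither independent nor unselected. Afp, Depp1, Ldb2 and Tmem100 were among the genes examined, and lists were examined beside their own members. The 11 is therefore no firm expectation for the 38.

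Knockout library 1 was the highest knockout-labelled library for Steap4 (362 normalised reads against 16.4 to 31.7 in the other 5), Ftl1 (44949 against 30791 to 33185), Cp (389 against 144 to 224), Depp1 (717 against 194 to 273), Apob (8581 against 148 to 346) and Afp (58827 against 339 to 2420). It was the lowest for Slc39a8 (330 against 572 to 645), Gcm1 (91.3 against 1182 to 1632), Ldb2 (67.6 against 346 to 404) and Tmem100 (421 against 1989 to 2676). In mean log2 values of lists it was the highest for yolk sac endoderm markers (11.1), interferon-stimulated genes (9.9), inflammatory mediators (7.51), trophoblast giant cell markers (14.1) and immediate early and heat shock genes (11.0), and the lowest for syncytiotrophoblast II markers (8.43) and fetal erythroid markers (7.22).

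Yolk sac endoderm markers such as Apob and Afp stood far out in knockout library 1. Of the 15 detected yolk sac markers, 15 were higher there than in each of the other 9 libraries. This count draws on the same markers that raised the flag, so it adds no separate support for RNA of yolk sac endoderm in this library. RNA of fetal liver, which shares many of these markers, would raise erythroid markers. The erythroid list score was instead 7.22 in this library, against a mean of 8.56 in the other 5 knockout-labelled libraries and 8.32 in the lowest of the other 9. This low score was itself flagged, and syncytiotrophoblast II markers (8.43) were also lowest here. A lower starting level could hide a rise, so the score cannot decide on fetal liver. Fewer labyrinth cells as the whole cause are argued against, since they would raise markers of every other cell type alike, while the yolk sac score minus the mean of the decidua and stroma scores lay 4.29 above its mean in the other 9 libraries (SD 0.94, largest excess among them 1.64). Whether the sample included attached yolk sac stays open, and no biological explanation was tested for 1 library.

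Control library 1 was the highest control for Itpka (1353 normalised reads against 938 to 1008 in the other 3), Pgd (3566 against 3236 to 3269), Cd163 (69.0 against 13.2 to 16.0), Fech (1987 against 1345 to 1395) and Smad6 (879 against 492 to 555), and the lowest for Isg15 (440 against 567 to 590). In mean log2 values of lists it was the highest for hypoxia-inducible factor targets (11.0 against 10.8 in the other 3), inflammatory mediators (6.53) and placental nutrient transporters (12.2), and the lowest for proliferation (7.21).

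Control library 4 was the highest control for Tfrc (17972 normalised reads), Slc11a2 (1682) and Hba-x (584), and the lowest for Slc39a14 (6824). Control library 3 was the highest control for Flvcr1 (872) and Pfkfb3 (1140). Knockout library 6 was the highest knockout-labelled library for Capn12 (376) and Pfkfb3 (866), and knockout library 4 for Hbb-y (12170). Knockout library 5 was the highest for the maternal decidua list (mean log2 value 9.61) and for total reads (26751556).

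Tfrc was low and NRF2 targets were high in the knockout-labelled libraries. With the erythroid score as a covariate the Tfrc log2 fold change was -1.58 (SE 0.35) against -1.75 without it, and the median of the 19 NRF2 targets was 0.18 against 0.23. A lower value of this score therefore does not account for these changes. The score averages falling and rising members and stood apart in knockout library 1 (7.22, against 8.32 to 9.15 elsewhere). It therefore cannot decide on less erythroid RNA as the cause. The high Tfrc value of control library 4 and the outlying knockout library 1 are argued against by a Tfrc log2 fold change of -1.34 (SE 0.12) without the former and an NRF2 median of 0.18 without the latter. Of 100 splits of the 10 libraries into 6 and 4, 2 gave as many NRF2 targets past the threshold over the list alone as the 6 of the real split, itself included (highest other 6). Only lists with the most such members of the 28 were counted this way. The splits did not allow for that choice, so chance is not excluded. Iron retained in placental cells of the libraries labelled knockout may lower Tfrc and raise antioxidant genes, a hypothesis left untested because iron was not measured here and Slc40a1 reads did not check the labels.

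Adult globins were low and embryonic globins high in the knockout-labelled libraries. Less blood as the whole cause is argued against, since it would lower all globins together. The mean log2 fold change of Hbb-y, Hbb-bh1 and Hba-x was instead 1.20 (SE 0.27) and that of the 4 adult globins -1.46 (SE 0.42). These are the values that raised the flag, so they add no separate support. Of the 18 measured erythroid markers 14 had a log2 fold change below 0 and 4 above, so less blood as a part of the cause stays open. A single library is argued against by the embryonic-minus-adult difference staying at 2.63 (SE 0.65) where it was least firm, without control library 4. For the erythroid list, 1 of 100 splits, the real one, gave 10 members past the threshold over the list alone (highest other 7). This list had the most such members of the 28. The splits did not allow for its choice on that count, so chance is not excluded. Less maternal blood as the whole cause is argued against by the same rise of 1.20 (2.29-fold), while a lower share of it beside a younger fetal red cell population in the libraries labelled knockout may still contribute, which was not tested.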

How the results depend on the processing

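The settings limma-voom, the fits leaving out 3 libraries, the edgeR fit without knockout library 6, the edgeR, DESeq2, weighted and robust fits without knockout library 1, and the fit without the block were chosen after seeing the data. Across 33 alternatives the Slc40a1 log2 fold change ran from -0.30 to 0.17 and never passed (smallest adjusted p = 0.573), and Tfrc ran from -1.96 to -1.34 and passed over the list alone in all 33 (largest adjusted p = 0.0149). Of 244 comparisons of main results, 221 kept their side of the threshold or their count, 2 of them with a changed sign (Slc40a1 with the erythroid covariate and without the 3 libraries, never past the threshold), and 23 counts moved by more than 1.5 times. Of the genes named singly, 4386 of 4650 comparisons kept their side, 213 passed where the reported fit did not, 50 no longer passed and 1 reversed. Set tests kept theirs in 841 of 922, with 44 gained, 35 lost and 2 reversed. The sign changed in 88 of the single-gene, 47 of the set-test and 2 of the main comparisons, and apart from the 3 reversals neither fit passed there.

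The number of genes past the threshold, 0 in the reported fit, was 7 with sample quality weights, 68 with DESeq2, 52 with the erythroid covariate, 2 without the block over numbers 1 to 4, and 21 without the 3 libraries high in yolk sac or decidua markers. Without knockout library 1 it was 14 with edgeR, 214 with DESeq2, 72 with weights and 20 with robust moderation, and edgeR without knockout library 6 gave 1. Leaving out 1 library at a time gave 0 to 14 genes. The other pseudocounts, filters and scalings, the robust fit and the decidua covariate gave 0. NRF2 targets past the threshold over the list alone numbered 11 with weights and 6 to 10 leaving out 1 library. Macrophage members numbered 3 without the block, 1 with the erythroid covariate and 3 to 6 leaving out 1 library. Camera called 0 lists with estimated correlations and fry 2, and the NRF2 call was lost with the estimated correlation (median 0.23, adjusted p = 0.0558). With the erythroid covariate, the interferon list (median -0.050), the syncytiotrophoblast II list (median 0.30) and Gcm1 (log2 fold change 0.93) reversed. The cause was not tested, except that fewer libraries enter the fits that leave some out.

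Libraries sharing a number were not stated to share a litter, and their deviations correlated at 0.308, 0.0574, 0.0228 and 0.0557 for numbers 1 to 4. No pairing by replicate number was seen for numbers 2 to 4, while a litter or batch shared by control library 1 and knockout library 1 stays open. Control libraries 2, 3 and 4 correlated best with knockout libraries 3, 4 and 6. The bracketed codes of these partners fall in the same runs of numbers as those of the controls. No fit was blocked on the codes, so litters or batches that follow them stay open. The replicate block over numbers 1 to 4 gave 0 genes, against 2 in the same 8 libraries without it, with Tfrc at a log2 fold change of -1.78, and only control library 1 correlated best with its own number. The block ended the calls of Fech, Nkg7, Hba-a2 and the endothelium list, and the same 8 libraries without it those of Nkg7, Heph, C1qc, C1qb and the endothelium list. Slc2a3 did not pass without a mean-variance trend (adjusted p = 0.083 over the list alone) or with robust moderation (0.051). In simulation, without differences in tissue composition, limma recovered 50.8% of 1.5-fold changes, so changes of this size or smaller can be missed. This rate holds for genes with a mean of at least 50 and was not measured for lower ones. In the real libraries larger ones can be missed too. Capn12 and Nqo1 did not pass over all genes at log2 fold changes of 1.64 and 1.62 (limma adjusted p = 0.0634 for both).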

Other observations

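The edgeR fit without knockout library 1, the test of mitochondrial transfer RNA genes and the splits for genes past the adjusted threshold were chosen only after the result was seen, and so were the gene names outside the fixed rule (Tmem100, Meox2, Ldb2, Gsta3, Depp1 and the transfer RNA genes other than mt-Ty). Without knockout library 1, 14 genes passed over all genes tested in limma, and edgeR called the same 14. Of these, 12 were higher in the knockout-labelled libraries, among them the endothelial genes Eng (log2 fold change 0.74, SE 0.11, adjusted p = 0.0362), Tmem100 (0.71, SE 0.09, adjusted p = 0.0174) and Meox2 (1.25, SE 0.19, adjusted p = 0.0362), the transcriptional cofactor gene Ldb2 (0.85, SE 0.09, adjusted p = 0.00919) and the glutathione transferase gene Gsta3 (1.21, SE 0.14, adjusted p = 0.0108). Capn12, Cat and Nqo1 were also among them. The 2 lower genes were Depp1 (-1.16, SE 0.15) and the spectrin gene Sptb (-1.03, SE 0.15). Of the 14 endothelial markers, 7 rose adjusted over the list alone without this library, Kdr among them (log2 fold change 0.51), against 0 with all 10 libraries. Of 18 proliferation genes 11 rose, and of 15 yolk sac markers 7 fell. At the preset correlation the yolk sac list lay lower (median -0.87, camera adjusted p = 1.83e-09), and so did trophoblast giant cell markers (camera adjusted p = 0.000525). The yolk sac correlation was estimated at 0.89 with all 10 libraries and was not estimated in this fit, so its p may be far too small. Control library 3 had the highest yolk sac score of the controls (8.63 against 6.74 to 7.53).

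Among 11 mitochondrial transfer RNA genes, 4 passed when adjusted over these genes, all higher in the knockout-labelled libraries: mt-Tf (log2 fold change 1.30, SE 0.40), mt-Ta (1.21, SE 0.22), mt-Tc (0.70, SE 0.21) and mt-Ty (1.16, SE 0.20). They are 66 to 69 bases long, with mean reads of 29.8 to 111.8 per library, and reads of their unprocessed precursors cannot be told apart from them.

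Of 100 splits of the 10 libraries into 6 and 4, 29 gave at least the real split's 776 genes at an unadjusted p under 0.05 (highest other 2411). At least its 10 lists past camera were given by 34 splits (median of the other splits 8, highest 14), so chance cannot be excluded for these totals. Splits with several times the 776 genes point to a structure of the samples other than the genotype. For genes past the adjusted threshold the real split gave 0 (highest other 9), so all 100 splits give at least as many by construction, and the count says nothing about chance. For macrophage markers, 1 of 100 splits, the real one, gave 5 members past the threshold over the list alone (highest other 1). This list was counted as one of those with the most such members of the 28. The splits did not allow for that choice, so chance is not excluded there.

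A targeted allele may carry linked sequence from another strain, which could shift genes near Slc40a1. Of 103 tested genes within 10 Mb, 3 had an unadjusted p under 0.05 (odds ratio 0.561, Fisher's exact test, two-sided p = 0.494), and the 95% interval of 0.113 to 1.69 includes 1, so no enrichment was seen and a small effect stays open.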
